A study of Mus musculus with 25 samples.

How the data were processed

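The series profiled 4 histone marks by chromatin immunoprecipitation and sequencing in mouse cells: H3K4me3, found at active and poised promoters; H3K27ac, found at active promoters and enhancers; H3K4me1, found broadly at enhancers and around promoters; and H3K27me3, deposited by Polycomb repressive complexes. Fibroblasts called tdMEFs in the labels were grown in serum-containing medium at 20% oxygen (D0) and then kept for 4 days (D4) or 8 days (D8) in M9 medium at 5% oxygen. M9 is serum-free and carries CHIR99021, which activates Wnt signalling, LDN193189 and A83-01, which block BMP and TGF-beta receptors, the Smoothened agonist Hh-Ag1.5, retinoic acid, SMER28, the DNA methyltransferase inhibitor RG108, the LSD1 inhibitor Parnate and basic FGF. Per the labels' protocols, chromatin was sheared to 200 to 400 bp, libraries were amplified with 13 PCR cycles and single reads of 50 nt were sequenced. The series design text writes ciNSLC beside day 0, whereas each sample label gives tdMEFs there, and the sample labels were followed. The labels describe 25 libraries: the 4 marks and an input for each of 5 stages, with 1 library per mark and stage.

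The deposited table holds 1 value per gene and library for 24453 gene symbols in 20 value columns. Only 12 of these columns could be matched to a labelled library by name, the 4 marks at D0, D4 and D8. The other 8 value columns match no label and were not used here, so the libraries of ciNSLC and pri-NPC, 2 further cell types named in the labels, and the 5 input libraries are not analysed here. The submitters' processing notes name the mouse build mm10 and the tools CASAVA 1.8.4, Bowtie 1.1.0, SAMtools 0.1.19 and bedtools. Which tool did what, the region counted around each gene, read extension and duplicate removal are not given in the sources used here. The deposited values are in RPM (reads-per-million) of the whole library, a unit inferred from the values themselves: between 93.5% and 95.2% of the values in a column are whole multiples of a single step within a tolerance of 0.02 of a read, and the step implies a whole number of reads in every column. No input appears to have been subtracted.

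Symbols that a spreadsheet had turned into dates (27) and genes at 0 in all 12 columns (205) were left out, which left 24221 genes with no repeated symbol. Of these, 308 have values identical to those of another gene in all 12 columns, so their reads cannot be assigned to 1 gene. Chromosomes and coordinates come from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, in which 23175 symbols (95.7%) had an entry and 1046 had none.

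Changes between stages are log2((a + c)/(b + c)), where c is the 25th percentile of the positive values of the mark: 1.44 RPM for H3K4me3, 1.53 for H3K27ac, 1.63 for H3K4me1 and 1.30 for H3K27me3. This scale understates the change of low genes. A gene was compared if the larger of its 2 values reached the median of the mark, 5.41, 2.18, 2.49 and 1.76 RPM in the same order, and was counted as higher or lower from a 2-fold difference upward. There are no replicates, so no p-value is given, every difference describes these libraries, and a difference between libraries is not shown to be a difference between conditions. Intervals of single genes and of the Y-linked genes are 95% Poisson intervals of the implied reads. These cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Intervals of the ratio of X-linked to autosomal genes come from resampling genes within 1 library and show the spread among genes. Counting error was also simulated in 20 draws with no true change other than the libraries' depth.

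Sets of genes were judged with 23 lists: neural stem and progenitor, proneural and neuronal, astrocyte, oligodendrocyte, fibroblast, Hox, pluripotency, Hedgehog targets, Wnt targets, retinoic acid targets, BMP and TGF-beta targets, FGF-ERK targets, hypoxia, cell cycle, cell cycle inhibitors, housekeeping, mesoderm and endoderm regulators, skeletal muscle, blood and macrophage, endothelial, epithelial, neural crest and melanocyte, and chromatin regulators. For each list the median log2 change was compared with 10000 random lists of the same size, matched on mean level in 20 bins. The excess is the list median minus the median of the random lists, and a list is said to stand apart if it lies below the 2.5th or above the 97.5th percentile. Chance gives 13.8 such results among the 276 combinations of list, mark and comparison. A gene carried both H3K4me3 and H3K27me3 if it reached the median of the former (5.41 RPM) and the 75th percentile of the latter (2.49 RPM).

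The lists, thresholds, pseudocounts, alternative settings and the rule for naming genes were set before the data were examined. Named genes are 30 fixed genes; for each mark the 5 with the largest gain and the 5 with the largest loss that were changed at least 2-fold the same way in a further stage; the 3 highest and 3 lowest in a last comparison; and up to 4 leading members of each list. Gene models without a name and genes on the sex chromosomes were passed over in the parts that rank genes. The rule was written for ciNSLC and pri-NPC, which were replaced by D8 and D4. Some genes that the rule names are not reported here. Xist and the Y-linked genes, the further lists in the closing observations, and 3 alternatives (equal depth, autosomal genes only, and D8 set against D4) were chosen after the data had been seen.

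The implied depth was 12.6, 2.77 and 34.9 M reads for H3K4me3 at D0, D4 and D8, 1.58, 16.9 and 7.86 M for H3K27ac, 24.5, 34.0 and 29.8 M for H3K4me1 and 5.11, 18.4 and 11.5 M for H3K27me3. The median gene held 44, 15 and 387 reads of H3K4me3, 3, 36 and 19 of H3K27ac, 54, 89 and 91 of H3K4me1 and 9, 32 and 21 of H3K27me3. Single-gene values at D0 are therefore imprecise for H3K27ac and H3K27me3. In simulated data with the real depths and 24221 genes, 4-fold changes were recovered for 100 of 100 genes in H3K4me3 at D4 and at D8, for 81 and 83 of 100 in H3K27ac, 99 and 98 in H3K4me1, and 81 and 80 in H3K27me3. A list of 25 genes from above the median level, with 0.5 added to their log2 changes, reached the 100th percentile in each of these comparisons. Only counting error was simulated, and smaller shifts or lists of low genes were not tried. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, the scaling of libraries (quantile normalization within a mark, or division by the median of the genes above the median level), the level filter, the matching of random lists and the thresholds for both marks.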

Results

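Chromatin of mouse fibroblasts was profiled before (D0) and 4 and 8 days after (D4, D8) a change to M9 medium, with 1 library per stage for each of H3K4me3, H3K27ac, H3K4me1 and H3K27me3. The comparisons ask how the marks at gene regions differ along this treatment, which per the series title is a chemical reprogramming of fibroblasts to neural stem cells. The 12 libraries held between 1.58 M reads (H3K27ac at D0) and 34.9 M reads (H3K4me3 at D8). No stage was replicated, so all values below describe single libraries.

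Housekeeping genes carried more H3K4me3, in RPM, at each later stage. Actb, the cytoplasmic actin gene, had 20.3 RPM at D0 (95% Poisson interval 17.9 to 22.9), 31.4 at D4 and 61.02 at D8, and Gapdh, a glycolytic enzyme, had 22.4, 46.3 and 81.8 RPM. Summed over genes, the H3K4me3 values came to 18.8% of the library's reads at D0, 28.5% at D4 and 53.9% at D8. A read in a region shared by several genes counts more than once in this sum. The lower quartile of genes went from 1.58 RPM at D0 to 1.44 at D4 and 1.12 at D8. Among compared genes the median log2 change of H3K4me3 was 0.60 at D4 and 1.51 at D8, both against D0. The corresponding medians were 0.24 and 0.48 for H3K4me1, -0.09 and 0.35 for H3K27ac, and -0.09 and 0.00295 for H3K27me3. RPM of H3K4me3 are as deposited and include this shift, so changes of lists are given relative to genes of the same level and log2 changes of single genes after quantile normalization, unless stated otherwise.

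Y-linked genes set the D0 libraries apart from the later ones in all 4 marks. Xist, the RNA that silences an X chromosome in female cells, had 1.03 RPM of H3K4me3 at D0 (95% Poisson interval 0.548 to 1.76), 41.1 at D4 and 47.9 at D8. The mean over the 5 Y-linked genes Ddx3y, Eif2s3y, Kdm5d, Uty and Usp9y, divided by the autosomal mean, was 1.29, 0.482 and 0.345 for H3K4me3 at D0, D4 and D8. The same ratio was 0.946, 0.310 and 0.285 for H3K27ac, 0.587, 0.186 and 0.224 for H3K4me1, and 0.674, 0.130 and 0.192 for H3K27me3. For the 925 X-linked genes, the mean H3K27me3 over the autosomal mean was 0.508 at D0, 0.896 at D4 and 0.904 at D8, while for H3K4me3 it was 0.494, 0.530 and 0.452. D0 and the later chromatin thus differed in sex-chromosome signal as well as in treatment, in every comparison against D0 below.

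**Figure D1:**
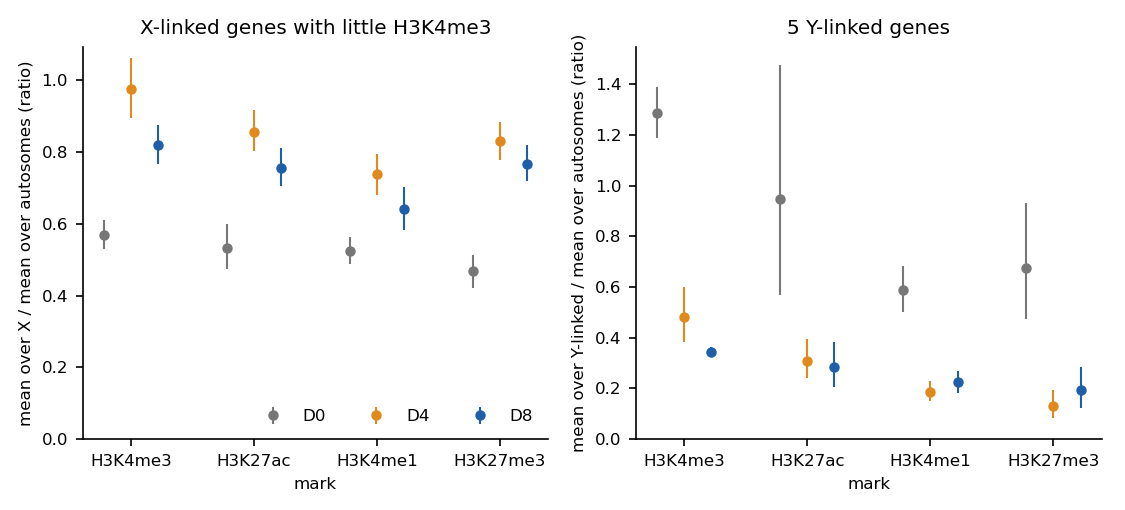
Mean signal of X-linked genes with little H3K4me3, and of 5 Y-linked genes, divided by the autosomal mean, for each mark at D0, D4 and D8, with 95% intervals from resampled genes (X-linked) or counting error (Y-linked). The Y-linked ratio for H3K4me3 is 1.29 at D0 and 0.345 at D8, and the X-linked ratio for H3K27me3 is 0.468 at D0 and 0.767 at D8.

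The order of genes by level was most alike between D4 and D8 for every mark. Across 24221 genes, which are not independent replicates, Spearman's rho for H3K4me3 was 0.914 between D4 and D0, 0.918 between D8 and D0, and 0.939 between D8 and D4. For H3K4me1 the values were 0.809, 0.788 and 0.943. H3K27ac gave 0.507, 0.498 and 0.786. Libraries simulated from the mean profile of the stages, differing by counting error and depth alone, gave 0.725, 0.700 and 0.888 on average. H3K27me3 gave 0.548, 0.481 and 0.702, against 0.737, 0.710 and 0.817 in such simulated libraries.

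After 4 days, genes of the low-oxygen response had the largest excess of H3K4me3 over genes of the same level. At D4 these included Egln3, an oxygen-sensing prolyl hydroxylase (3.56 RPM at D0 and 27.8 at D4, log2 change 2.04), and Bnip3, a mitophagy receptor (6.57 and 42.5 RPM, 1.8). Hedgehog targets stood above their matched genes too: Hhip, a Hedgehog-binding protein, had 2.61 RPM at D0 and 33.2 at D4 (3.03), and Gli1, the transcription factor at the end of the pathway, 4.91 and 28.8 (1.64). Genes of the cell cycle lagged behind, as Cdk1, the mitotic kinase, had 20.5 RPM at D0 and 16.2 at D4 (-0.87) while most other genes were higher.

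In list terms, the excess log2 change at D4 was 0.61 for hypoxia (18 of 19 members above the matched median), 0.31 for cell cycle inhibitors, 0.28 for Hedgehog targets, 0.27 for retinoic acid targets, 0.25 for FGF-ERK targets, -0.15 for fibroblast genes and -0.42 for cell cycle genes (20 of 26 below). Those 7 of 23 lists stood apart, where chance gives 1.15. Single genes counted as deposited were 1676 higher and 30 lower of 12327, and after quantile normalization 423 higher and 359 lower. The retinoic acid call ended under quantile normalization and at equal depth, the FGF-ERK call at equal depth, and the fibroblast call with lists matched on the D0 level; the D4 library is the shallowest of this mark.

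At D8 the genes ranked highest for H3K4me3 included the Hedgehog target Hhip. The first by rank was Cadps, a priming factor for vesicle release (chromosome 14, 12372560 to 12823339), which had 1.35 RPM at D0 (0.784 to 2.16), 18.0 at D4 and 52.6 at D8, a log2 change of 3.74 after quantile normalization. Hhip (chromosome 8, 79965850 to 80058060) reached 57.7 RPM, a quantile-normalized change of 2.91. Next by the fixed rule came F11r, a junctional adhesion molecule (3.09 to 59.4 RPM, 2.47), Fam181b (3.56 to 64.8, 2.31) and Inhbb, a subunit of activin and inhibin (3.64 to 62.4, 2.20). At the other end, H3K4me3 was lower at D8 at Meox1, a mesodermal homeobox gene (6.89 RPM at D0, 1.12 at D8), Cmklr1, the chemerin receptor (6.89 and 1.18), C1qtnf3 (6.10 and 1.61) and Aspn, an extracellular matrix protein (26.1 and 10.3), although the median gene was higher by 1.51.

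Targets of Hedgehog, Wnt and FGF signalling, which M9 stimulates, stood above genes of the same level, the FGF-ERK list not at equal depth. Retinoic acid targets had an excess of 0.28, within the central 95% of random lists. Hedgehog targets had an excess of 0.47 at D8 against D0, with 10 of 14 members above matched genes. Beside Hhip they included Gli1 (4.91 to 57.6 RPM, 1.70) and the receptor Ptch1 (20.98 to 115.8, 0.95). Wnt targets had an excess of 0.38, led by Lef1 (4.43 to 49.8 RPM, 1.60) and Tcf7 (1.47 to 20.6, 2.32), transcription factors of the pathway, and by its feedback inhibitor Axin2 (9.50 to 90.7, 1.58). FGF-ERK targets had an excess of 0.25, with the feedback inhibitors Spred2, Spry4 and Dusp4 in the lead. Hypoxia genes had the largest excess of the 23 lists, 0.82, with 17 of 19 members above matched genes; Egln3 reached 60.0 RPM (log2 change 2.20), Bnip3 78.3 (1.8) and the glycolytic regulator Pfkfb3 64.4 from 9.87 (1.01). In the same direction stood apart epithelial genes (0.68), cell cycle inhibitors (0.42), neural stem and progenitor genes (0.30) and chromatin regulators (0.22). Cdkn1a, a cyclin-dependent kinase inhibitor induced by p53, had 11.2 RPM at D0 and 90.3 at D8 (1.38).

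Cell cycle and fibroblast genes stood apart in the other direction. Of 26 cell cycle genes, 23 lay below the median of matched genes, and the excess was -0.72. Ccnb2, a mitotic cyclin, had 7.76 RPM at D0 and 7.63 at D8 (-1.43), and the replication licensing factor Cdc6 had 6.81 and 8.68 (-1.15). Fibroblast genes had an excess of -0.47 with 47 of 65 members below matched genes. Col1a2, a chain of type I collagen, had 62.4 RPM at D0 and 74.2 at D8 (-0.98), Col1a1 45.7 and 82.9 (-0.58), and the surface marker Thy1 14.7 and 30.4 (-0.57). S100a4, a calcium-binding protein of fibroblasts, was lower on either scale, with 5.86 RPM at D0 (4.60 to 7.36) and 2.12 at D8 (1.67 to 2.67). Twist1 and Snai2, mesenchymal transcription factors, had 45.3 and 34.6 RPM at D0 and 106.7 and 70.8 at D8. Their direction flipped with quantile normalization (-0.19 and -0.48). The same holds for Cdc6, Col1a2, Col1a1 and Thy1, which were higher at D8 as deposited and lower only on the quantile-normalized scale.

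These 10 of 23 lists stood apart at D8. The remaining 13 lists had excesses of 0.36 (proneural and neuronal), 0.28 (retinoic acid targets), 0.25 (pluripotency), 0.22 (astrocyte), 0.19 (skeletal muscle), 0.04 (blood and macrophage), 0.02 (BMP and TGF-beta targets), 0.02 (mesoderm and endoderm regulators), 0.01 (endothelial), -0.0017 (Hox), -0.02 (housekeeping), -0.06 (oligodendrocyte) and -0.16 (neural crest and melanocyte). Counts of single genes depended on scaling: 12143 higher and 8 lower of 13401 as deposited, 247 and 230 relative to the median shift, and 476 and 416 after quantile normalization. Equal depth ended the calls of the epithelial (0.46), FGF-ERK (0.19) and chromatin regulator lists (0.20, and 0.16 on autosomal genes), and a 4-fold larger pseudocount that of the neural stem list (0.047).

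H3K4me3 at several neural genes was higher at D8 as deposited, but not at all of them on the quantile-normalized scale. Nes, an intermediate filament of neural progenitors (chromosome 3, 87971093 to 87980451), had 3.25 RPM at D0 (2.33 to 4.40), 14.8 at D4 (10.6 to 20.1) and 39.6 at D8 (37.5 to 41.7), a quantile-normalized log2 change of 1.77 at D8. Pou3f2, a factor of neural progenitors, had 2.30, 6.85 and 17.0 RPM (1.61). Sox2, a factor of neural stem and pluripotent cells (chromosome 3, 34649995 to 34652461), had 4.67 RPM at D0, 3.61 at D4 and 16.0 at D8, a change against D0 that was 1.52 as deposited and turned to -0.04 with quantile normalization. Sox1 had 0.634, 2.16 and 7.52 RPM (1.69), Pax6 1.90, 2.70 and 7.31 (0.99), and Olig2 1.27, 1.44 and 5.36 (1.09). Values stayed low at the neuronal gene Dcx (0.95 RPM at D0, 1.26 at D8), at the astrocyte gene Gfap (0.713 and 0.947) and at the pluripotency gene Pou5f1 (0.594 and 0.789).

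**Figure D2:**
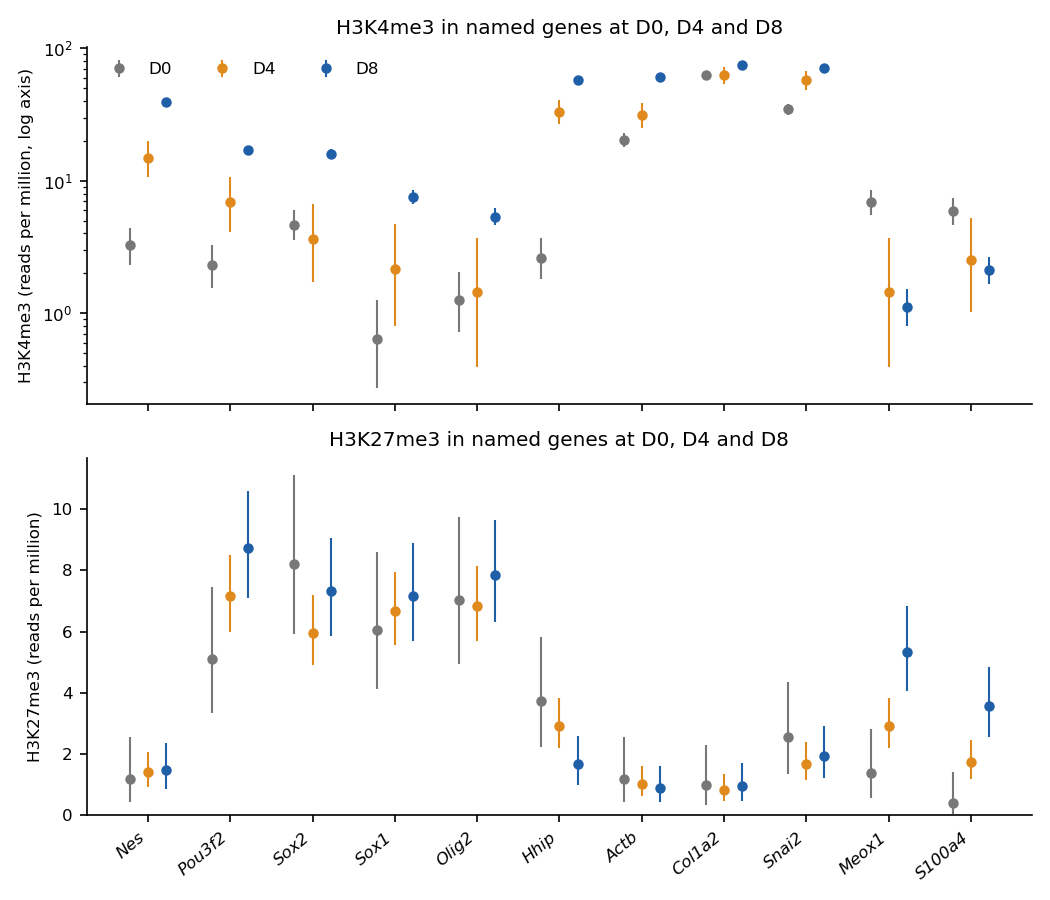
H3K4me3 (log axis) and H3K27me3 in RPM at D0, D4 and D8 for 11 named genes, with 95% Poisson intervals that cover counting error only. Nes has 3.25, 14.8 and 39.6 RPM of H3K4me3 at the 3 stages, while Sox2 has 4.67, 3.61 and 16.0 and its direction at D8 against D0 flips with quantile normalization.

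Between D4 and D8, neural stem and progenitor genes were the list furthest above matched genes for H3K4me3. Their excess was 0.36, with 40 of 48 members above. This comparison sets no D0 library against another, but D0 still entered the matching on level, the pseudocount and the quantile normalization. Sox21, a relative of Sox2, had 2.16 RPM at D4 and 18.7 at D8, Sox8 4.69 and 22.0, and Sox2 3.61 and 16.0, quantile-normalized changes of 1.91, 1.02 and 0.98. Proneural and neuronal genes had an excess of 0.30, with the neurogenic factors Ebf2 (4.69 and 16.7 RPM, 0.66) and Neurod1 (2.88 and 8.78, 0.71) in the lead. Fibroblast (-0.21), cell cycle (-0.22) and blood and macrophage genes (-0.30) lay below. The other lists that stood above at D8 against D0 did not stand apart here, with 0.05 for hypoxia, 0.14 for Hedgehog, 0.17 for Wnt, 0.04 for FGF-ERK, 0.0070 for cell cycle inhibitors, 0.11 for epithelial genes and 0.05 for chromatin regulators. As deposited, 5490 genes were higher and 8 lower of 13414, and after quantile normalization 66 and 54. Equal depth ended the proneural call, and quantile normalization that of the blood and macrophage list, whose members had a median of 1.09 RPM at D8.

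**Figure D3:**
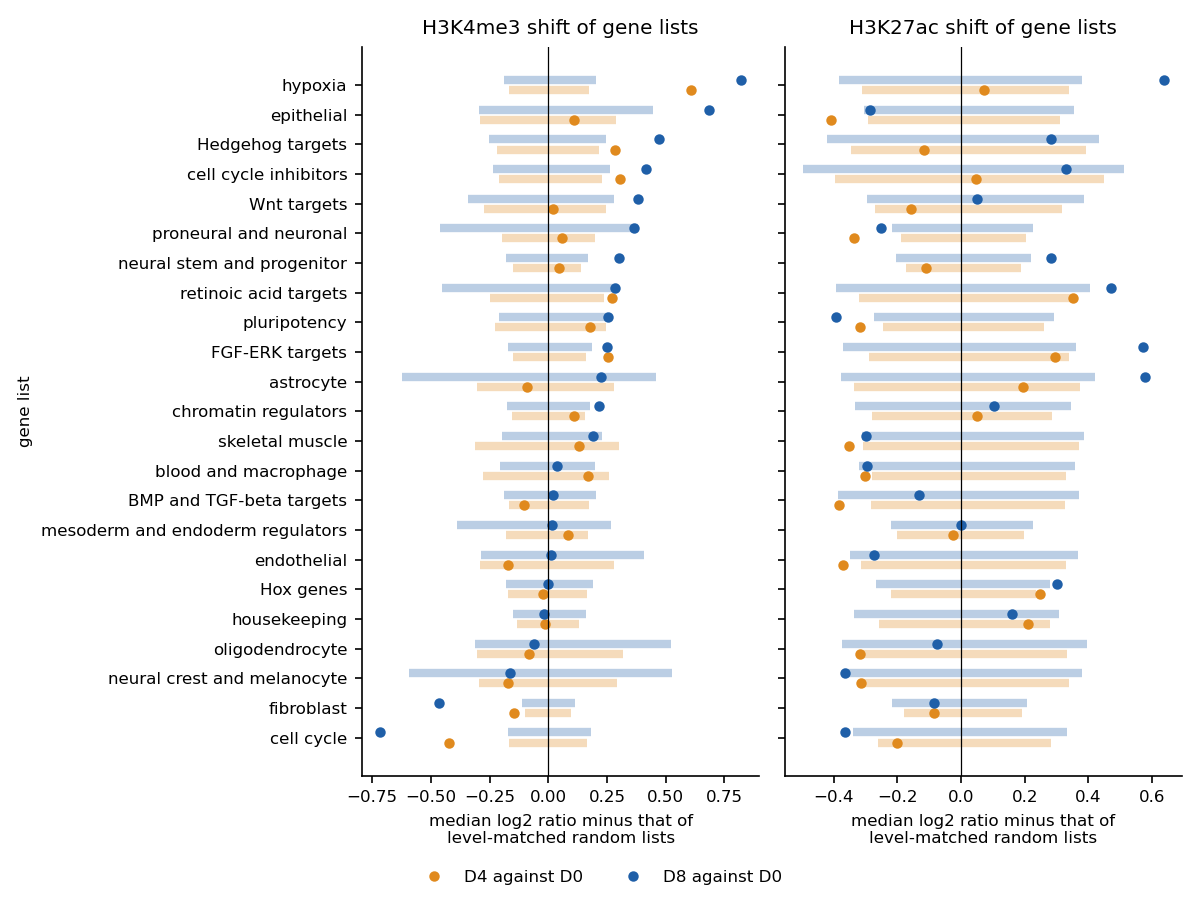
Excess of each gene list's median log2 change over random lists matched on level (points), with the central 95% of the random lists (bars), for H3K4me3 and H3K27ac at D4 and D8 against D0. For H3K4me3 at D8 against D0, hypoxia genes lie highest (0.82) and cell cycle genes lowest (-0.72).

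H3K27ac was higher at D8 at genes that answer retinoic acid, low oxygen and FGF. Dhrs3, a retinaldehyde reductase induced by retinoic acid, had 1.26 RPM at D0 (0.153 to 4.56), 12.5 at D4 and 44.9 at D8 (40.3 to 49.8). Ddit4, a stress-induced inhibitor of growth signalling in the hypoxia list, had 1.26, 9.39 and 30.9 RPM. Other genes, outside the lists of these responses, were higher as well. Irf2bpl had 0.632, 8.62 and 26.8 RPM, and Blcap 0.632, 8.44 and 20.98. Nfkbia, the inhibitor of NF-kappaB, was listed at 0 at D0, 6.85 RPM at D4 and 16.0 at D8. A single read is worth 0.632 RPM in the D0 library, so D0 values of Irf2bpl, Blcap and Nfkbia rest on a single read or none. Lower were Cdh3, a cadherin (13.3 RPM at D0, 1.65 at D8), and Anxa8 (11.4 and 2.29). Gli1 (1.26 and 20.7 RPM) and Ptch1 (4.42 and 28.9) led the Hedgehog targets, though that list did not stand apart (0.28).

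The lists above matched genes at D8 were hypoxia (0.64), astrocyte (0.58, led by the gap junction gene Gja1, 3.16 and 16.0 RPM), FGF-ERK targets (0.57, with Dusp6 at 5.05 and 30.0 RPM and 15 of 20 members past the filter at least 2-fold higher), retinoic acid targets (0.47), Hox genes (0.30) and neural stem and progenitor genes (0.28, led by Sox11 and Nr2f1). Below lay proneural and neuronal (-0.25), cell cycle (-0.36) and pluripotency genes (-0.39). Relative to the median, 1643 genes were higher and 1542 lower of 16729, where the deposited values gave 3328 and 388 and counting error alone 509.9 and 261.1. Hox and cell cycle genes lost their call under quantile normalization, and neural stem, proneural and pluripotency genes at equal depth.

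At D4, retinoic acid targets (0.35) and Hox genes (0.25) lay above matched genes, and 9 lists lay below, from epithelial (-0.41), BMP and TGF-beta targets (-0.38), endothelial (-0.37) and skeletal muscle (-0.35) to proneural (-0.34), oligodendrocyte (-0.32), pluripotency (-0.32), neural crest (-0.31) and blood genes (-0.30). Among BMP and TGF-beta targets, Id1, a direct BMP target, had 13.3 RPM at D0 and 4.90 at D4, and Col1a1 20.8 and 7.73. The other 8 lists had medians of 1.34 to 2.63 RPM at D0, near the 3 reads of the median gene in that library. Equal depth ended the calls of the Hox, retinoic acid, epithelial, endothelial, skeletal muscle, proneural and pluripotency lists; 892 genes were higher and 599 lower of 15555, relative to the median 1166 and 368, and 460.1 and 185.7 from counting error alone.

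Between D4 and D8 the lists above were neural stem (0.41), retinoic acid (0.41), hypoxia (0.42), Hedgehog (0.41), BMP and TGF-beta (0.30), Wnt (0.23) and chromatin regulators (0.19), with 1082 genes higher and 5 lower of 15455. Id1 and Col1a1 had 15.1 and 19.5 RPM at D8 as deposited. The 99th percentile of genes was 8.84 RPM at D0 and 18.2 at D8, so equal RPM is not equal standing at these stages. Quantile normalization turned the retinoic acid excess to -0.05 and reduced the gene counts to 86 higher and 84 lower, and equal depth ended the calls of the neural stem, Hedgehog, Wnt and BMP lists.

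Of the 4 marks as deposited, H3K4me1 had the fewest genes that differed at least 2-fold from D0 at the pseudocount set for each mark. The pseudocount understates changes of low genes, so this count does not show that H3K4me1 changed least. At D8 neural stem and progenitor genes had an excess of 0.16 over matched genes (39 of 48 above) and Hedgehog targets 0.22, and in both lists the ventral neural tube factor Nkx2-2 was among the leading members (1.1 RPM at D0, 5.11 at D8). Sox2 had 1.43 RPM at D0 (0.993 to 1.98), 3.97 at D4 (3.32 to 4.69) and 3.96 at D8. Also above were pluripotency (0.22), epithelial (0.19), mesoderm and endoderm (0.15) and proneural genes (0.15), of which each lost its call under a setting of pseudocount, scaling or matching. At D4 the lists above were Hedgehog (0.23), epithelial (0.17), mesoderm and endoderm (0.16), neural stem (0.14), BMP and TGF-beta (0.12) and chromatin regulators (0.10), and from D4 to D8 Wnt targets (0.12) and Hox genes (0.11).

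Single genes with at least 2-fold more H3K4me1 numbered 13 of 13732 at D4 and 356 of 14987 at D8, with 0 lower. With the pseudocount divided by 4, 216 were higher and 10 lower at D4, and 1981 and 92 at D8. H3K27me3 at D8 against D0 then gave 2030 and 1050. After quantile normalization 16 were higher and 11 lower at D4, and 16 and 24 at D8. Between D4 and D8, 0 genes passed in either direction. Krt33a, a hair keratin, had 1.06 RPM at D0, 3.82 at D4 and 6.21 at D8, and Xdh, the xanthine dehydrogenase gene, 2.65, 8.14 and 9.34.

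Among the fixed genes, several neural regulators had similar H3K27me3 at D0 and D8. Sox2 had 8.22 RPM of H3K27me3 at D0 (5.92 to 11.1) and 7.33 at D8 (5.84 to 9.07), Pax6 6.85 and 7.76, Olig2 7.04 and 7.85 and Sox1 6.07 and 7.15, differences that lay within counting error. Hes5, a Notch target, had 2.74 RPM at D0 (1.5 to 4.60) and 7.67 at D8 (6.16 to 9.46), and S100a4 0.391 (0.0474 to 1.41) and 3.58 (2.57 to 4.85). The ranked genes were Tns1, a focal adhesion protein (0.196 RPM at D0, 4.71 at D8), its neighbour Rufy4, whose annotated start overlaps Tns1, Glis1 (0.196 and 4.10) and Epx (0.587 and 4.97) on the higher side. On the lower side were Yaf2, a subunit of Polycomb complexes (6.26 and 0.785), Ccdc92 (10.4 and 2.44), Cbr3 (5.48 and 0.959) and Ift20 (5.28 and 0.959).

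Astrocyte genes lay above matched genes for H3K27me3 at D8 (0.32), led by Fgfr3, and housekeeping genes (-0.20), chromatin regulators (-0.24) and FGF-ERK targets (-0.26) below. At D4 the lists were astrocyte (0.41), Hox (0.21), housekeeping (-0.19), hypoxia (-0.32) and FGF-ERK (-0.37), and from D4 to D8 oligodendrocyte (0.27), blood (0.23), Hedgehog (0.22), Wnt (0.18), pluripotency (0.15) and neural stem genes (0.11), with 16 genes higher and 1 lower (26 and 16 after quantile normalization). Quantile normalization ended the calls of all 4 lists at D8, and equal depth those of all 5 lists at D4. Of 17069 genes 721 were higher and 263 lower at D8 against D0, where counting error alone gave 39.95 and 14.4, and quantile normalization 322 and 313; on the X chromosome 136 of 606 genes were higher and 0 lower. At D4 the counts were 369 and 228 of 16237, and relative to the median 545 and 114.

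How many developmental regulators carried both H3K4me3 and H3K27me3 depended on the scale, and no list was tested for it. As deposited, of 48 neural stem and progenitor genes, 9 carried both at D0, 11 at D4 and 27 at D8, while those with H3K27me3 alone went from 27 at D0 to 9 at D8. Proneural genes with both numbered 2, 10 and 17 of 38, Hox genes 16, 25 and 30 of 39, and mesoderm and endoderm regulators 8, 10 and 18 of 42. After quantile normalization the counts at D0, D4 and D8 were 14, 11 and 17 for neural stem, 4, 8 and 6 for proneural, 28, 26 and 26 for Hox, and 13, 12 and 10 for mesoderm and endoderm genes, so the later counts were not higher for the Hox or the mesoderm and endoderm list. Over all genes, 2049 carried both at D0, 1238 at D4 and 2273 at D8. Of the genes with both at D0, 17.7% had both at D8 and 81.7% had H3K4me3 alone. Another 1088 genes with H3K27me3 alone at D0 had both at D8. The median gene held 9 reads of H3K27me3 at D0, so counting error alone can move genes across the H3K27me3 threshold. After quantile normalization of both marks, 2158 genes had both at D0, 1350 at D4 and 1466 at D8, so the count at D8 was below that at D0. Of those with both at D0, 24.4% then had both at D8 and 65.9% had H3K4me3 alone. On that scale 260 genes went from H3K27me3 alone at D0 to both at D8.

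Genes that differed at least 2-fold in H3K4me3 had small median differences of the same sign in H3K27ac and H3K4me1. In the 476 genes at least 2-fold higher in H3K4me3 at D8 after quantile normalization, the median log2 change was 0.26 for H3K27ac and 0.24 for H3K4me1, and in the 416 lower genes -0.29 and -0.17. The median change of H3K27me3 was 0.01 and 0.03 in the same sets. Across genes, Spearman's rho between the changes at D8 was 0.217 for H3K4me3 with H3K27ac, 0.187 for H3K27ac with H3K4me1, 0.0772 for H3K4me3 with H3K4me1, -0.0108 for H3K4me3 with H3K27me3, -0.0575 for H3K4me1 with H3K27me3 and -0.133 for H3K27ac with H3K27me3. Quantile normalization raised the value for H3K4me3 with H3K4me1 to 0.198 and turned those for H3K4me3 with H3K27me3 and H3K4me1 with H3K27me3 to 0.0617 and 0.0622.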

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

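Equal depth, autosomal genes only and D8 set against D4 were alternatives chosen after seeing the data, and the others were planned. Of the 29 lists that stood apart at D8 against D0, none reversed under the settings run, and 25 kept their call with the pseudocount times 4, 27 with it divided by 4, 22 after quantile normalization, 27 after division by the upper-50% median, 24 with lists matched on the D0 level, 19 at equal depth and 28 on autosomal genes. All 24 counts of genes stayed within 1.5 times on autosomal genes, a setting that removes few genes and so could change little. Input division and similarity with input were not run because no input column was used, a mean of several entries per symbol because symbols were unique, and comparisons of ciNSLC and pri-NPC because their columns were not used. Counts below are genes at least 2-fold higher, then lower, and list values are excess log2 changes; pseudocounts and filters act on low genes by construction, and for the other changes the cause was not tested. Depth limits single genes most for H3K27ac and H3K27me3 at D0.

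With the pseudocount times 4, H3K4me3 gave 456 and 8 genes at D4 against D0, 1 lower at D8 against D0, and 2773 and 0 at D8 against D4. H3K27ac gave 14 and 15, 499 and 5, and 88 and 0 in the same order, H3K4me1 0 higher and 1 higher against D0, and H3K27me3 1 and 1, 2 and 1, and 0 and 0. List values at D8 against D0 were 0.047 for neural stem genes in H3K4me3, 0.048 for proneural and 0.080 for epithelial genes in H3K4me1, and 0.14 for astrocyte genes in H3K27me3. With the pseudocount divided by 4, H3K27ac gave 1991 and 1836, 5081 and 1191, and 2496 and 104 genes, H3K4me1 216 and 10, 1981 and 92, and 12 and 4, and H3K27me3 1348 and 1079, 2030 and 1050, and 289 and 91. Astrocyte genes had 0.46 and housekeeping genes -0.33 in H3K27me3 at D8 against D0.

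After quantile normalization, H3K4me3 gave 423 and 359 genes at D4 against D0, 476 and 416 at D8 against D0, and 66 and 54 at D8 against D4. H3K27ac gave 1117 lower, 1212 and 1119, and 86 and 84, H3K4me1 11 lower at D4 and 16 and 24 at D8 against D0, and H3K27me3 322 higher at D8 against D0 and 26 and 16 at D8 against D4. List values at D8 against D0 were 0.22 for Hox and -0.28 for cell cycle genes in H3K27ac, 0.14 for pluripotency genes in H3K4me1, and 0.23 for astrocyte, -0.19 for FGF-ERK, -0.093 for housekeeping and -0.14 for chromatin regulator genes in H3K27me3. Retinoic acid targets in H3K27ac reversed to -0.045 at D8 against D4. A single gene was called reversed only if its deposited change was at least 2-fold. In H3K4me3 at D8 against D0, Sox2 reversed to -0.043, Elk1 to -0.42, Twist1 to -0.19 and Snai2 to -0.48. Genes with smaller deposited changes, such as Col1a1, Col1a2 and Thy1, turned sign as well but fall outside that rule. Genes with both marks at D8 numbered 1466. Spearman's rho between changes was 0.180 for H3K4me3 with H3K27ac, 0.198 for H3K4me3 with H3K4me1, 0.0617 for H3K4me3 with H3K27me3 (reversed), 0.144 for H3K27ac with H3K4me1, and 0.0622 for H3K4me1 with H3K27me3 (reversed).

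Division by the upper-50% median gave 255 and 235, 331 and 348, and 46 and 56 genes for H3K4me3, 1575 higher, 1592 and 1409, and 79 and 110 for H3K27ac, 0 and 7, 5 and 145, and 1 lower for H3K4me1, and 123 lower at D4 against D0 and 2 lower at D8 against D4 for H3K27me3. Cell cycle genes had -0.37 in H3K27ac and housekeeping genes -0.19 in H3K27me3. In H3K4me3 at D8 against D0, Tubb3 reversed to -0.18, Elk1 to -0.29, Twist1 to -0.39, Twist2 to -0.037, Snai2 to -0.58, Actb to -0.041 and Ccdc85a to -0.0079.

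A filter at the 75th percentile gave 741 and 3 genes for H3K4me3 at D4 against D0, 1 lower at D8 against D0 and 0 lower at D8 against D4, 408 higher at D4 against D0 and 0 lower at D8 against D4 for H3K27ac, and 176 and 463 higher for H3K27me3 at D4 and D8 against D0. Without a filter, 339, 74 and 165 genes were lower in H3K4me3 at D4 against D0, D8 against D0 and D8 against D4, and 1347 higher in H3K27ac at D4 against D0.

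At equal depth, 53 and 37 genes were lower in H3K4me3 at D4 and D8 against D0. H3K27ac gave 2329 and 2450 at D4 against D0, 1602 lower at D8 against D0, and 4343 and 1210 at D8 against D4, and H3K27me3 784 and 673, 1206 and 606, and 437 and 180; thinning to few reads adds counting error by construction. List values at D8 against D0 were 0.19 for FGF-ERK, 0.46 for epithelial and 0.20 for chromatin regulator genes in H3K4me3, 0.19 for neural stem, -0.10 for proneural and -0.11 for pluripotency genes in H3K27ac, and 0.27 for astrocyte, -0.13 for FGF-ERK, -0.13 for housekeeping and -0.066 for chromatin regulator genes in H3K27me3. D8 set against D4 in place of D0 gave 5490 higher genes for H3K4me3, 1082 and 5 for H3K27ac, 0 higher for H3K4me1, and 16 and 1 for H3K27me3. On autosomal genes chromatin regulators had 0.16 in H3K4me3. Lists matched on the D0 level gave 0.17 for neural stem and -0.10 for cell cycle genes in H3K27ac, and 0.090 for pluripotency, 0.17 for mesoderm and endoderm and 0.29 for epithelial genes in H3K4me1.

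Genes with both marks numbered 88, 28 and 254 at D0, D4 and D8 with thresholds at the 75th and 90th percentiles, and 4681, 4218 and 5588 with the median of both. Spearman's rho between stages on the upper 50% of genes was 0.872 (D4 and D0), 0.842 (D8 and D0) and 0.909 (D8 and D4) for H3K4me3, 0.152, 0.118 and 0.728 for H3K27ac, 0.526, 0.521 and 0.789 for H3K4me1, and 0.277, 0.190 and 0.628 for H3K27me3. A narrower range of levels lowers it by construction, but for every mark rho fell less between D8 and D4 than in either pair with D0. For H3K27ac the values over all genes had been 0.507, 0.498 and 0.786. The cause of this difference was not tested. On autosomal genes rho was 0.495 and 0.483 for H3K27ac (D4 and D8 with D0), 0.800, 0.779 and 0.941 for H3K4me1, and 0.695 for H3K27me3 (D8 and D4).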

Other observations

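The 12 further gene lists below and the tests of depth on X-linked genes, of Y-linked genes and of the lower quartile of H3K4me3 were chosen only after the results had been seen. These 12 lists were run on the deposited values only and not repeated under the alternative settings. Targets of p53 had more H3K4me3 and H3K27ac at D8 than matched genes: Perp, a death effector and cell adhesion gene, had 1.43 RPM of H3K4me3 at D0 and 32.2 at D8, the apoptosis gene Pmaip1 6.02 and 68.5, and Trp53inp1 11.2 and 82.8. The excess over matched genes at D8 against D0 was 0.35 for H3K4me3 (18 of 23 members above), 0.72 for H3K27ac and -0.38 for H3K27me3, and the list did not stand apart for H3K4me1 (-0.039). Genes of the Notch pathway, of which 4 of 24 are also in the fixed lists, stood above matched genes between D4 and D8. The excess was 0.21 for H3K4me3, 0.40 for H3K27ac and also 0.15 for the repressive mark H3K27me3. Hes1, a Notch target that keeps neural progenitors undifferentiated, went from 25.6 to 88.8 RPM of H3K4me3 and from 3.48 to 14.4 of H3K27ac over these 4 days.

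Smooth muscle and contractile genes, of which 3 of 18 are also in the fixed lists, lay below matched genes for H3K4me3 at D8 against D0 (-0.36). The actin gene Acta2 stood at 33.8 and 22.7 RPM and the calponin gene Cnn1 at 6.57 and 3.90. Genes of cholesterol synthesis had an excess of 0.24 for H3K4me3 and 0.54 for H3K27ac at D4 against D0, and of -0.31 and -0.23 at D8 against D4, 2 comparisons that share the D4 libraries with opposite sign. Interferon response genes had 0.30 for H3K4me3 at D4 and -0.39 at D8, both against D0, and cytoplasmic ribosomal protein genes -0.26 and -0.23. At D8 against D0 the circadian clock list had 0.30 for H3K4me3, autophagy and lysosome genes 0.17 for H3K4me3 and 0.34 for H3K27ac, and early response genes of the AP-1 family, of which 11 of 23 are also in the fixed lists, 0.41 for H3K27ac. Oxidative phosphorylation genes stood apart only for H3K27me3 at D4 against D0 (-0.17). These lists gave 48 of 144 results outside the central 95% of random lists. The 7.2 that chance would give is no fair yardstick here, since the lists were chosen after the results and the comparisons share libraries.

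X-linked genes with little H3K4me3 carried less signal relative to autosomes at D0 than at D4 and D8 in all 4 marks, but over all 925 X-linked genes the H3K4me3 ratio was 0.494, 0.530 and 0.452. Whether shallower libraries at D0 played a part was not settled. Among genes with little H3K4me3 the ratio in the H3K4me3 library at D4, the shallowest of that mark, was 0.976. That is above the upper bound of 0.610 at D0, but these genes were picked by their mean H3K4me3 over D0, D4 and D8. The tested library thus helped to choose them. Over all 925 X-linked genes the intervals for H3K4me3 overlapped, with 0.488 to 0.571 at D4 and 0.458 to 0.533 at D0. A change of marks on the X chromosome alone is argued against by the Y-linked genes, whose H3K4me1 ratio was 3.16 times as high at D0 as at D4 (lower bound 2.19). In 4 of 4 marks the Y-linked ratio at D0 lay above both later stages, interval against interval, consistent with chromatin at D0 from cells with more Y chromosomes and, as far as the X-linked genes with little H3K4me3 go, fewer X chromosomes. Whether the D0 cells were another preparation, another mix of male and female embryos, or cells before a selection in culture stays untested, and each of these could add differences at autosomal genes.

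H3K4me3 was at least 2-fold higher at D8 than at D0 in 12143 of 13401 genes. The deeper library at D8 is argued against as the whole cause, since 11717 genes were still at least 2-fold higher at equal depth. A better enrichment of the immunoprecipitation at D8 and a gain of the mark across promoters cannot be told apart: the lower quartile of genes was 1.12 RPM at D8 and 1.58 at D0, as a lower background would give, but a fixed number of reads spread over more signal would lower it as well. No spike-in is described in the labels.

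Cell cycle and fibroblast genes had less and hypoxia genes more H3K4me3 at D8 against D0 than genes of the same level. An effect of enrichment on genes of different level is argued against, since after quantile normalization all 3 lists stayed outside the random lists with shifts of at least 0.37 in size. On autosomal genes the smallest of the 3 shifts was 0.4988 in size, so X-linked members did not carry them. Few genes are X-linked, so little could change, and an effect of different cells at D0 on autosomal genes was not tested. Further lists, which shared 0 (cell cycle) and 1 (hypoxia) of 30 members with the fixed lists, gave -0.60 for the cell cycle (0 of 30 members above matched genes) and 0.37 for hypoxia, and for H3K27ac -0.036 (not apart) and 0.85, while the fixed cell cycle list had -0.36 for H3K27ac and lost that call under quantile normalization (-0.28) and D0 matching (-0.10), so slower proliferation and a low-oxygen response stay hypotheses, the former resting mainly on H3K4me3. M9 medium and 5% oxygen began together, so their parts were not separated, and a difference in the cells used at D0 stays open.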
